A study of Mus musculus with 2 samples.

How the data were processed

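H3K4me1, the monomethylated form of lysine 4 of histone H3 that marks enhancers and the flanks of active promoters, was mapped by ChIP-seq in stomach of B6NCrl mouse embryos at embryonic day 15.5. The series holds 2 samples in 1 group. Replicate 1 was a pool of stomachs from 78 embryos and replicate 2 a pool from 62 embryos, both of mixed sex. Per the labels, fragments of 300 to 500 bp were selected, and replicate 2 lists 2 technical replicates where replicate 1 lists 1. The series has no second tissue, stage or treatment, so nothing was compared between conditions.

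The deposited files were 4 lists of peaks in narrowPeak format on mouse genome build mm10. Per the deposited records of the files, a list was made for each replicate from its alignments and 2 further inputs, a pooled list from the alignments of both replicates, and a replicated list from the pooled list and both replicate lists. All intervals of the replicated list were also in the pooled list, so a replicated peak has the extent and values of the pooled peak. The aligner, the peak caller and the rule by which a peak counts as replicated are not given in the sources used here. Each list carries the authors' signal value per peak, whose reference level is not stated, and the authors' −log10 p and −log10 q per peak, as well as the summit. These values belong to each peak within its own list and were used only to describe, rank and filter peaks. The lists hold no read counts, so the sequencing depth of the samples is unknown and no interval based on depth was computed. Wilson intervals at 95% describe the counting error of shares of peaks or of transcription start sites, and neighbouring peaks are not independent.

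Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Figures were drawn with matplotlib 3.10.9. Gene models were the protein-coding genes of GENCODE release M21 (basic set) on the 19 autosomes and chromosome X, 21728 genes in all, and the sequence was GRCm38, the assembly behind mm10. A gene's transcription start site (TSS) was the 5′ end of the gene. Promoters lay within 1 kb of any transcript start of a protein-coding gene. Summits were assigned in the order promoter, 5′ UTR, other exon, intron and intergenic.

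The overlap of the replicate lists was tested one-sided against 100 circular shifts of one list within each chromosome, with at least 1 bp counted as shared. The location of summits was tested two-sided in the same way. The smallest p that 100 shifts allow is 0.0099. Shifts keep the spacing of peaks but can also place them in assembly gaps, where no peak can be called. Replicates were set side by side gene by gene after each list was shortened to its 83180 strongest peaks by −log10 p, the length of the replicated list; values are given as mean ± SD over n = 2 pools.

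The measure for genes was the sequence in kb covered by replicated peaks within 50 kb on either side of the TSS. It counts every peak in the window, including those that belong to neighbouring genes. In all, 27 gene lists and 3 gene families were fixed before the data were examined. They covered gastric epithelium, differentiated gastric products, squamous forestomach epithelium, gastric mesenchyme, smooth muscle, enteric nervous system, endothelium, blood and macrophages, mesothelium, the Hedgehog, BMP, Wnt, retinoic acid and Notch pathways, Hox genes of paralog groups 1 to 8 and 9 to 13, housekeeping genes, intestine, liver, pancreas, lung, kidney, forebrain neurons, cardiac muscle, skeletal muscle, photoreceptors, germ line, olfactory receptors, Zfp-named zinc fingers and vomeronasal receptors. Of the 567 list entries, 565 matched a gene symbol and 2 an older symbol. List members with TSSs at most 100 kb apart were counted as 1 locus. Each list was compared with 100000 random draws of genes matched on the number of protein-coding TSSs within 50 kb (5 bins), by a two-sided permutation test with Benjamini-Hochberg adjustment over the 30 lists. The smallest p these draws allow is 1e-05. Random draws hold single genes, whereas a list's locus can average several. A list member was called high when its covered kb reached the 90th percentile of genes in its density bin, which chance gives for about 10% of genes. The test treats loci as the units, so its p-values describe how a list stands among other genes in this tissue and not the variation between embryos. Beside each list's mean, the 95% interval from 10000 bootstrap resamples of its loci is given. Named members are ranked by covered kb and not by percentile, so a leading member need not be high.

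As fixed in advance, 6 lists of stomach cell types (gastric epithelium, squamous forestomach epithelium, gastric mesenchyme, smooth muscle, enteric nervous system and endothelium) were compared with 9 lists of other organs (liver, pancreas, lung, kidney, forebrain neurons, cardiac muscle, skeletal muscle, photoreceptors and germ line) by a two-sided permutation test of the locus labels with 100000 resamples. Domains were made by joining replicated peaks at most 3 kb apart and ranked by covered sequence. Genes were named by rules fixed before the data were examined. These rules took the 4 members with the most covered kb and the 1 with the least in each list, the 20 domains with the most covered sequence, the 10 peaks with the highest signal value, the 20 genes with the most covered kb of which only 1 was kept per shared window, and the 10 genes with the largest difference between the replicates. Genes named only as neighbours of these, such as those whose TSSs share a window, fall outside the rules, and any other gene named outside them is said to be so.

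The list test was tested on simulated data, with 100 random lists of 20 genes whose values were multiplied by a known factor. At a p of 0.05 it called 4% of lists at a factor of 1, 46% at 1.5, 76% at 2 and 100% at 3. These rates use the p before adjustment, so they overstate how often a call by adjusted p would be made. Lists with fewer loci were not simulated. The coverage code matched a base-by-base count in the simulated intervals. Alternatives fixed in advance were a stricter threshold of −log10 q of at least 2, other overlap rules, windows of 20 and 100 kb, counts of peaks in place of kb, leaving out promoters, each replicate's own list, every member as its own locus, no matching, matching on GC content of the window as well, wider promoters, peak centres, the pooled list, and a shorter (1 kb) and a longer joining distance for domains. A run on autosomes only was added after the data were seen.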

Results

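H3K4me1 was profiled in stomachs of mouse embryos at embryonic day 15.5, when the organ holds epithelium, mesenchyme, developing smooth muscle, nerves and vessels. The data are 2 biological replicates, pools of 78 and 62 embryos, in 1 group. The authors deposited a list of enriched intervals for each pool, a list from both pools together and a list of replicated peaks. Depth per sample is unknown, since the lists carry no read counts. The comparisons that the design allows are between the replicates, between peaks and shifted positions in the genome, and between groups of genes within this tissue.

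Replicate 1 had 150222 peaks and replicate 2 had 150227. Their median widths were 253 and 256 bp (mean 254.5 ± 2.12 bp, SD, n = 2), and they covered 50.3 and 50.8 Mb (mean 50.5 ± 0.354 Mb, n = 2). Median signal values, as the authors gave them, were 2.80 in both lists. The pooled list had 190436 peaks and the replicated list 83180, with a median width of 454 bp and a total of 48.5 Mb, or 1.84% of the autosomes and chromosome X. Of the replicate lists, 50.1% and 49.7% of peaks reached a −log10 q of 2, against 96.6% of the replicated list. Pooled peaks that were in the replicated list were wider and stronger than the rest. Their median width was 454 bp against 208 bp, and their median −log10 p was 7.48 against 4.33.

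The pools shared 53.7% of the peaks of replicate 1 and 53.1% of those of replicate 2, against means of 4.03% and 4.00% after circular shifts (permutation p = 0.0099 each, one-sided, the smallest that 100 shifts allow). Shared sequence made up 31.0% of all sequence covered in either list, against 1.12% after shifts (permutation p = 0.0099). Where an overlap had to span at least 50% of both peaks, 27.9% of the peaks of either replicate were shared, against 1.09% after shifts. Of the replicated peaks, 83.5% overlapped a peak in both replicate lists, 8.42% one in replicate 1 only, 7.71% one in replicate 2 only, and 288 peaks none in either. At the 69473 peaks seen in both lists, the rank correlation of the authors' signal values was low (Spearman rho 0.362 across peaks, which are not independent replicates). Across the 21728 genes, rho for covered kb in the pools was 0.948; the windows overlap, follow GC content and include genes without peaks, so this value is not comparable with that of single peaks.

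With promoters taken as 1 kb around TSSs, most replicated summits lay inside genes and outside promoters. Introns held 51.3% of summits (95% Wilson interval 51.0% to 51.7%) against a mean of 37.0% after shifts. Intergenic sequence held 28.3% (28.0% to 28.6%) against 58.3%. Promoters held 15.8% (15.6% to 16.1%), which was 7.17 times the 2.21% after shifts, other exons 4.44% against 2.53%, and 5′ UTRs outside promoters 0.138% against 0.0367%. Each of the 5 shares lay outside all 100 shifts (permutation p = 0.0099, two-sided). With promoters widened to 2.5 kb, they held 28.2% of summits, 5.47 times the 5.14% after shifts, and introns held 42.3% against 35.4%. The median distance from a summit to the nearest protein-coding TSS was 17.8 kb, and 40.6% of summits lay within 10 kb of one. The 10 peaks with the highest signal values included 9 in introns, among them peaks in or near Uck2, Prrc2b, Bahcc1, Pcgf2, Arhgef2 and Hspg2. The highest, with a signal value of 7.54, covered chromosome 4, 139595501 to 139599640, in an intron, 5.25 kb from the TSS of Gm21969.

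**Figure D1:**
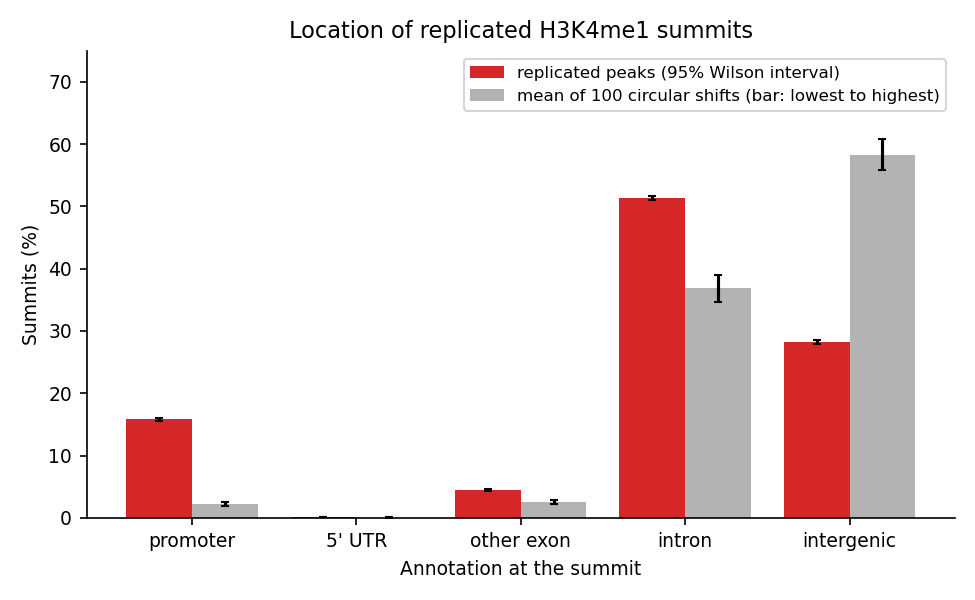
Bars give the percentage of replicated H3K4me1 summits in each annotation class (red, 95% Wilson interval) and the mean of 100 circular shifts (grey, lowest to highest shift). Promoters held 15.8% against 2.21%, introns 51.3% against 37.0% and intergenic sequence 28.3% against 58.3%.

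H3K4me1 flanked TSSs and was scarcer at the TSS itself. A replicated peak covered 10.6% of the 21728 protein-coding TSSs (95% Wilson interval 10.2% to 11.0%), 15.4% of positions 550 bp upstream and 23.1% of positions 1000 bp downstream. The share at the TSS was thus 0.458 of the highest share. Both pools showed the same shape when their lists were shortened to equal length. Coverage at the TSS was 6.25% in replicate 1 and 8.40% in replicate 2, and the ratio to the highest share was 0.373 and 0.519. The depth of the dip therefore differed between the pools, and with 1 value per pool that difference has no test.

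**Figure D2:**
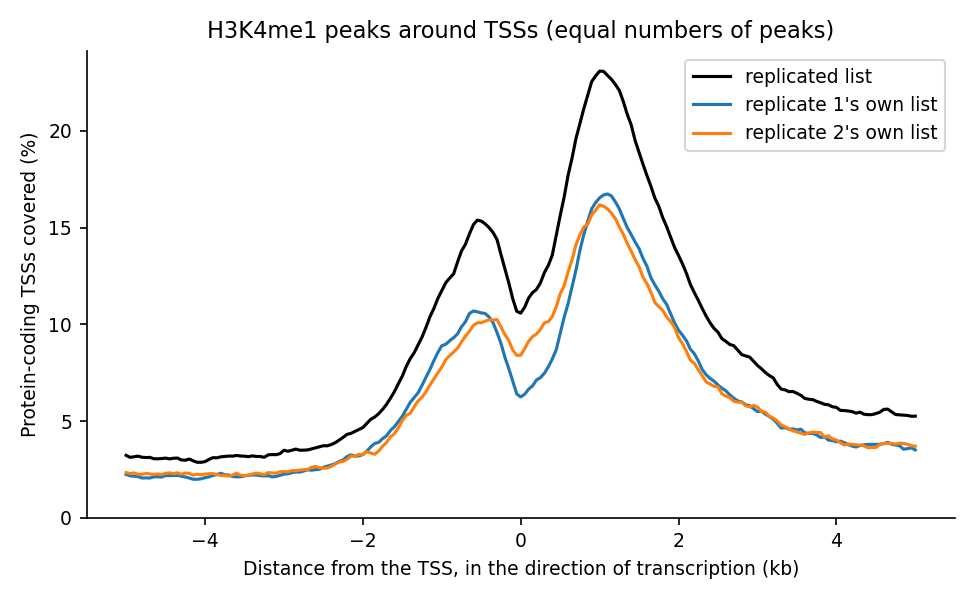
Lines give the percentage of protein-coding TSSs covered by a peak (vertical axis) at each distance from the TSS in kb (horizontal axis, positive in the direction of transcription) for the replicated list and for the equally long lists of each replicate. All 3 lines dip at the TSS, to 10.6%, 6.25% and 8.40%, and are highest about 1 kb downstream.

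Genes of 4 developmental signalling pathways stood in sequence with more H3K4me1 than genes of the same local density. Components of the Notch pathway, which controls binary cell fate choices, had a mean of 12.3 kb covered (95% bootstrap interval over loci 8.71 to 16.5 kb), 2.90 times that of matched genes (permutation p = 1e-05, the smallest that the draws allow; adjusted p = 0.0001). Of its 21 genes, 8 were high, or 38.1% where chance gives 10%. The receptors Notch1 (39.0 kb; 29.7 ± 4.22 kb, n = 2) and Notch2 (28.6 kb), the Notch-modifying glycosyltransferase Lfng (26.1 kb) and the target gene Hes1 (16.9 kb) had the most, and the DNA-binding mediator Rbpj (1.97 kb) the least. The retinoic acid list had a mean of 10.3 kb (5.28 to 16.3 kb), 2.81 times matched genes (adjusted permutation p = 0.0003), with 6 of 19 genes high. It was led by the nuclear receptors Rara (44.7 kb; 39.2 ± 1.13 kb, n = 2), Rxra (35.2 kb) and Rarg (16.5 kb) and the binding protein Crabp2 (23.3 kb), while the retinaldehyde dehydrogenase gene Aldh1a1 had 0.298 kb. Rara lies on chromosome 11, 98927818 to 98974942, and peaks covered 36.6 of the 47.1 kb of its body.

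**Figure D3:**
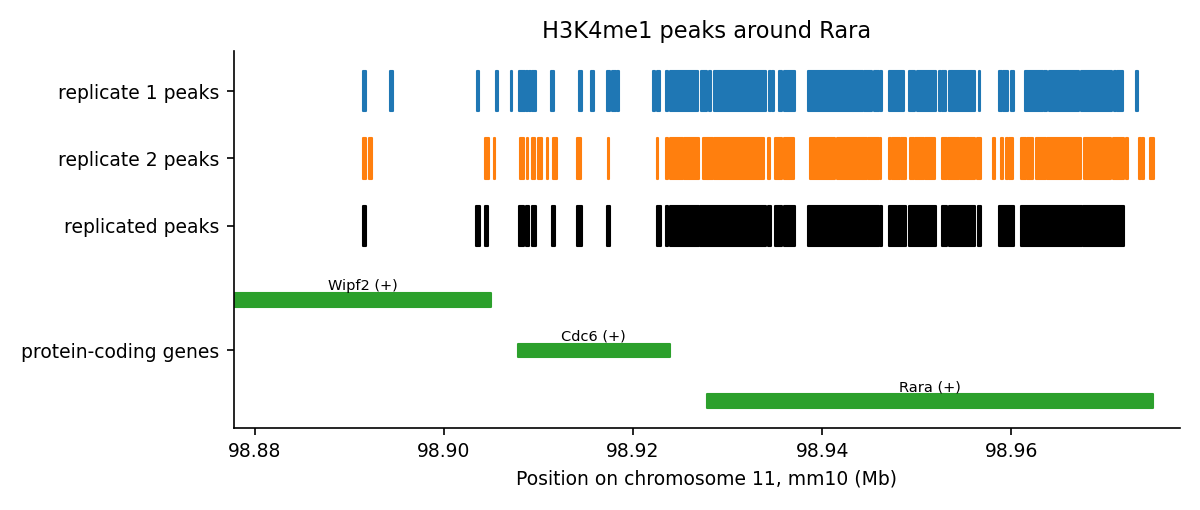
Intervals along chromosome 11 (horizontal axis, Mb, mm10) within 50 kb of the TSS of Rara are drawn for replicate 1, replicate 2 and the replicated list, above the protein-coding genes with their strand. Replicated peaks fill 36.6 of the 47.1 kb of Rara and 3.28 of the 16.1 kb of the neighbouring Cdc6.

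BMP pathway genes had a mean of 7.91 kb (4.57 to 11.9 kb), 2.66 times matched genes (adjusted permutation p = 0.0008), and 7 of 22 were high. The inhibitory SMAD genes Smad7 (32.7 kb) and Smad6 (20.9 kb) and the BMP target genes Id1 (21.7 kb) and Id3 (19.2 kb) led, whereas the ligand gene Bmp5 had no replicated peak within 50 kb. Wnt pathway genes had a mean of 6.78 kb (4.98 to 8.69 kb), 2.39 times matched genes (adjusted permutation p = 0.00066), and 14 of 31 were high. The transcription factor genes Tcf7l2 (20.1 kb) and Tcf7l1 (15.2 kb), the ligand gene Wnt11 (18.3 kb) and the receptor gene Fzd2 (13.3 kb) had the most, and Rspo3 (0.257 kb) the least. The 15 Hedgehog genes, with Ptch1 (16.8 kb) first and Gli3 (0.849 kb) last, had a ratio of 1.70 that did not pass (adjusted permutation p = 0.127). The list passed with windows of 20 kb (adjusted permutation p = 0.0495) or 100 kb and with counts of peaks. With matching on GC content as well, its ratio was 1.21 (adjusted permutation p = 0.567). Covered kb followed the GC content of the window across genes (Spearman rho 0.806), and with matching on GC content as well the ratios were 1.65 for Notch, 1.78 for retinoic acid, 2.12 for BMP and 1.68 for Wnt, with adjusted permutation p from 0.003 to 0.0184. Without matching on gene density, the Wnt list did not pass (1.57 times, adjusted permutation p = 0.054).

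Among the lists of stomach cell types, smooth muscle and gastric mesenchyme passed the test. Smooth muscle genes had a mean of 7.62 kb (5.32 to 10.04 kb), 2.02 times matched genes (adjusted permutation p = 0.0087), and 8 of 21 were high. Csrp1, which encodes a LIM protein, led with 20.0 kb (13.7 ± 0.554 kb over the pools, n = 2). The intermediate filament gene Des (16.0 kb) and Pdlim7 (16.0 kb) came next, then the tropomyosin gene Tpm2 (13.9 kb). Tpm2 was not high, at percentile 77.5 of its density bin. Myocd, a coactivator of smooth muscle genes, had 0.334 kb. Gastric mesenchyme genes had a mean of 4.96 kb (3.56 to 6.53 kb), 1.78 times matched genes (adjusted permutation p = 0.0474). Only 5 of 32 were high, or 15.6% where chance gives about 10%. Pbx1 (16.6 kb), the collagen gene Col1a1 (13.9 kb) and the transcription factor genes Tbx2 (12.04 kb) and Foxf1 (11.5 kb) had the most. Foxf1 stood at percentile 85.6 of its density bin, and Col3a1 had no replicated peak. With windows of 20 kb, both lists passed, mesenchyme at 2.10 (adjusted permutation p = 0.00431) and smooth muscle at 1.85 (adjusted permutation p = 0.0288). With matching on GC content, neither list passed. The smooth muscle ratio was then 1.40 (adjusted permutation p = 0.104) and the mesenchyme ratio 1.60 (adjusted permutation p = 0.0531); the mesenchyme call was also lost on autosomes only, without matching, with windows of 100 kb, without promoters and in the list of replicate 1.

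The epithelial lists did not pass. Gastric epithelium had 1.48 times the coverage of matched genes (adjusted permutation p = 0.187), and 4 of its 28 genes were high. Among its members, the tight junction gene Cldn7 had 18.2 kb and the endoderm factor gene Foxa3 13.1 kb. Neither was high, at percentiles 89.6 and 75.1 of their density bins. The keratin genes Krt8 and Krt18 had 17.0 and 14.1 kb and were high. The stomach-type claudin gene Cldn18 had no replicated peak within 50 kb. This list passed when peaks were counted (1.61 times, adjusted permutation p = 0.0313) and turned below matched genes with matching on GC content (0.824 times, adjusted permutation p = 0.517). Differentiated gastric products had a ratio of 0.961 (adjusted permutation p = 0.954), with 1 of 22 high. Muc1 (18.6 kb) and the pepsinogen gene Pgc (8.23 kb) came first, and the lipase gene Lipf had no peak. Pgc stood only at percentile 53.8 of its density bin. With matching on GC content, the ratio of this list was 0.603 (adjusted permutation p = 0.0851). Squamous forestomach genes had a ratio of 1.08 (adjusted permutation p = 0.919), with Irf6 (10.3 kb), Pitx1 (10.1 kb), the integrin gene Itgb4 (9.19 kb) and Sfn (7.77 kb) first and the basal-cell factor gene Trp63 without a peak. The Muc1 and Cldn7 windows each hold 8 other protein-coding TSSs.

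Lists of the other cell types that a whole stomach holds did not pass either. The ratio was 0.987 for the enteric nervous system (Tlx2 16.4 kb, Gfra1 8.17 kb, Elavl4 without a peak), 1.43 for endothelium (Eng 23.5 kb, Egfl7 16.8 kb, Ets1 9.37 kb, Emcn without a peak), 0.664 for blood and macrophages (Klf1 10.1 kb, Epor 9.50 kb, Csf1r 6.24 kb, the X-linked Alas2 without a peak) and 1.15 for mesothelium (Krt7 12.3 kb, Msln 12.2 kb, Muc16 0.214 kb). Adjusted permutation p-values for these 4 lists ran from 0.318 to 0.964. Klf1 and Epor stood at percentiles 62.2 and 59.6 of their density bins. Housekeeping genes had a ratio of 1.40 (adjusted permutation p = 0.145), with Rplp0 (25.1 kb) and Eef2 (21.6 kb) first and the X-linked Hprt at 0 kb; without matching they passed (1.65 times, adjusted permutation p = 0.0361).

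Genes of other organs served as a background measured in the same way. Forebrain neuron genes passed at 1.74 times matched genes (adjusted permutation p = 0.0474), although only 3 of 28 were high, about the share that chance gives. Neurod2 (16.5 kb), Camk2a (15.8 kb), Slc17a7 (12.7 kb) and Bcl11b (12.6 kb) led the list. The Slc17a7 window holds 10 other protein-coding TSSs, and Slc17a7 stood at percentile 73.4 of its density bin. The call was lost with matching on GC content (1.37 times, adjusted permutation p = 0.158), on autosomes only, with windows of 100 kb, with counts of peaks, without promoters, without matching and in the list of replicate 1. It was kept with windows of 20 kb (2.18 times, adjusted permutation p = 0.00261) and in the list of replicate 2. The stricter threshold and every member as its own locus kept it too. The ratio was 0.982 for intestine, with Cdx1 (16.0 kb) first, 0.694 for liver, with Apoa2 (13.5 kb) first, 1.31 for pancreas, with Rbpjl (14.9 kb) first, 1.46 for lung, with Ager (22.5 kb) first, and 0.859 for kidney, with Aqp2 (6.89 kb) first. It was 1.21 for cardiac muscle, with Myl3 (10.6 kb) first, 1.53 for skeletal muscle, with Tnnt3 (36.9 kb) first, 1.27 for photoreceptors, with Gnat1 (30.6 kb) first, and 0.710 for germ line genes, with Prm1 (12.7 kb) first. None of these 9 lists passed (adjusted permutation p from 0.191 to 0.964). Several of the leaders sit beside other genes: the Ager window holds 10 other TSSs, including that of Notch4, and the Gnat1 window those of Gnai2, Slc38a3 and Sema3f.

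In a direct comparison, 6 stomach lists (gastric epithelium, squamous forestomach, gastric mesenchyme, smooth muscle, enteric nervous system and endothelium) were not distinguishable from 9 lists of other organs, namely those described above without intestine. The 126 stomach loci had a mean of 5.12 ± 4.81 kb (SD over loci) and the 163 other loci 4.57 ± 4.91 kb. The difference was 0.551 kb (95% bootstrap interval −0.602 to 1.69 kb; permutation p = 0.342, two-sided), and 2 genes in both sets were left out. The interval allows a stomach mean from below that of the other organs to 1.69 kb above it. Unlike the list tests, this comparison was not matched on gene density or GC content. The density-matched means of its lists ranged from 2.78 kb for gastric mesenchyme to 4.47 kb for photoreceptors. It therefore cannot tell whether the groups differ at equal gene density.

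Olfactory and vomeronasal receptor genes, which act in nasal sensory neurons, lay in sequence nearly free of replicated peaks. Of 1134 olfactory receptor genes, 997 had no peak within 50 kb, and the loci had 0.118 times the coverage of matched genes (adjusted permutation p = 0.0001). Of 330 vomeronasal receptor genes, 315 had none, with a ratio of 0.0121 (adjusted permutation p = 0.0001). Olfr70 and Olfr71, which share a window, had the most of their family at 7.80 kb, and Vmn1r4 had 3.20 kb. With matching on GC content the ratios were 0.417 and 0.0649, and both lists still passed (adjusted permutation p = 0.003 and 0.0003). Their windows were low in GC content, with means of 38.7% and 39.2% against 44.5% over all genes. GC differences left inside the matching bins may therefore still contribute. Zfp-named zinc finger genes had a ratio of 0.892 (adjusted permutation p = 0.362), from Zfp395 at 23.2 kb and Zfp516 at 22.4 kb to 74 of 365 genes without a peak. Counted gene by gene instead of by locus, they passed at 0.699 times matched genes (adjusted permutation p = 6e-05). That count treats neighbours as independent, although the 365 genes lie in 217 loci. By locus and with matching on GC content, the ratio was 0.992 (adjusted permutation p = 0.949).

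Hox genes, which pattern the body axis, lie in 4 clusters only, and neither of their 2 lists passed. Genes of paralog groups 1 to 8 had a mean over clusters of 14.4 kb, 1.70 times matched genes (adjusted permutation p = 0.226), and 10 of 23 were high. Hoxb4 (24.8 kb), Hoxb3 (23.5 kb), Hoxb5 (23.0 kb) and Hoxb2 (21.1 kb) led and Hoxd1 (6.12 kb) was last. Groups 9 to 13 had a mean of 8.37 kb, 1.20 times matched genes (adjusted permutation p = 0.824), from Hoxa9 (15.5 kb) to Hoxb13 (1.40 kb), with 0 of 16 high. Neighbouring Hox genes share most of their windows. The list of groups 1 to 8 passed when each gene was its own locus (2.05 times, adjusted permutation p = 6e-05), when peaks were counted and without matching. With matching on GC content, its ratio fell to 1.22 (adjusted permutation p = 0.554).

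**Figure D4:**
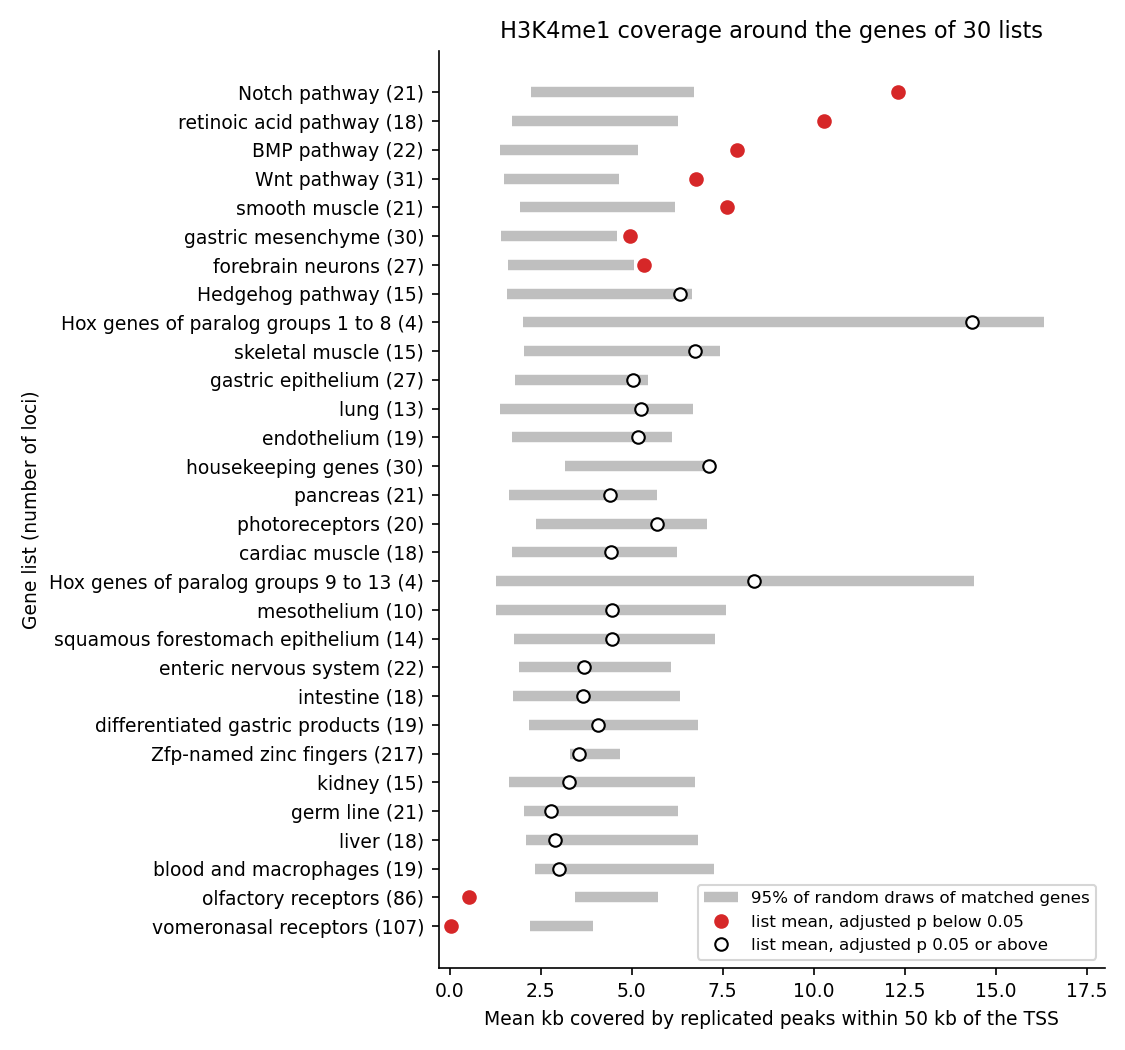
Points give the mean kb covered by replicated peaks within 50 kb of the TSS (horizontal axis) for each of the 30 gene lists (vertical axis, number of loci in brackets), filled where the adjusted p is below 0.05. Grey bars span the central 95% of random draws of density-matched genes; Notch lies highest above its bar in ratio (2.90) and the vomeronasal receptors lowest (0.0121).

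Joined within 3 kb, replicated peaks formed 40437 domains with a median of 0.698 kb covered and a 99th percentile of 8.10 kb. In 243 domains, 10 kb or more was covered. The domain with the most covered sequence lay over Gse1, which encodes a coiled-coil protein, and the overlapping gene model Gm20388, on chromosome 8 from 120484012 to 120558018, with 55.2 kb covered (42.7 ± 4.16 kb in the equally long replicate lists, n = 2). Next came Ncor2, a nuclear receptor corepressor gene (chromosome 5, 125119829 to 125196250, 51.0 kb), and the domain over Cdc6 and Rara (chromosome 11, 98922529 to 98971887, 41.1 kb; 36.7 ± 0.536 kb, n = 2). Ski, a repressor of TGF-beta signalling, followed with 40.6 kb, then Pmepa1, a TGF-beta-responsive gene, with 38.6 kb, Zmiz1 with 37.0 kb in its first and 29.9 kb in its second domain, and Sept9 with 36.5 kb. The other domains among the first 20 lay over Ssbp3, Actn4 with Eif3k, Zfpm1, Zmynd8, Elmsan1, Dab2ip, Lrig1, Smad7, Shb, Rxra, Bcl9l with Cxcr5, and Zfhx3, and had 24.2 to 35.3 kb covered. Of these 20, 10 were again among the first 20 when peaks were joined within 1 kb, 10 with a longer joining distance, 12 in the list of replicate 2 and 13 in that of replicate 1.

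Ranked by gene, Ncor2 had the most covered sequence within 50 kb of its TSS (50.9 kb), followed by Rara (44.7 kb), Mrpl23 (43.2 kb), Ski (42.1 kb), Bahcc1 (41.6 kb), Dohh (41.4 kb), Ifrd2 (40.9 kb) and Zmiz1 (40.5 kb). Smad3, a signal transducer of the TGF-beta family (36.9 kb), the thyroid hormone receptor gene Thra (38.4 kb), the nonmuscle myosin gene Myh9 (36.3 kb) and the cytokine signalling inhibitor gene Socs3 (35.8 kb) were also among the first 20. Over all genes the median was 2.09 kb, and 5083 genes (23.4%) had no replicated peak in the window. With the replicate lists at equal length, the largest differences towards replicate 2 were at Adssl1 (19.4 kb in replicate 1 and 26.9 kb in replicate 2), Tmem184b (18.3 and 25.7 kb), Wdr18 (19.1 and 26.5 kb), Pycr1 and 2310011J03Rik. Those towards replicate 1 were at Sys1 (11.2 and 5.28 kb), Igf2r (25.6 and 20.0 kb), Il17b, Map4k4 and Arhgap10. With 1 value per pool, these differences have no test.

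Replicated peaks were spread unevenly over the chromosomes. Chromosome 11 had the highest density, with 60.0 peaks per Mb of sequence, and chromosome 3 the lowest of the autosomes, with 22.3 per Mb. Chromosome X had 183 replicated peaks, or 1.12 per Mb. The replicate lists had 606 and 523 peaks on chromosome X, 3.71 and 3.20 per Mb, so the scarcity was present before replicated peaks were selected. None of the 4 lists had a peak on chromosome Y.

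**Figure D5:**
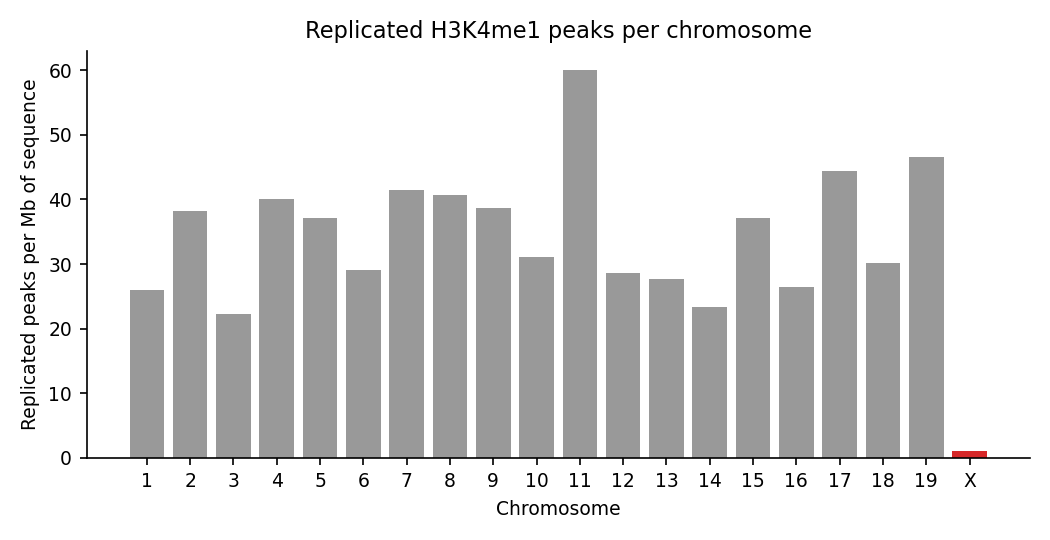
Bars give the number of replicated H3K4me1 peaks per Mb of sequence (vertical axis) on each chromosome (horizontal axis), with chromosome X in red. The autosomes lie between 22.3 and 60.0 peaks per Mb and chromosome X at 1.12.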

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

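Matching the gene lists on GC content was planned, but its values had been seen before it was set as the test of that explanation for the signalling and smooth muscle lists; the comparison of TSSs over 3 bins of GC content was chosen after results were seen.

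Peaks outside the replicated list, which the comparisons above did not use, lay in promoters more often than shifted positions did. Of the 107256 pooled peaks that were not replicated, 8.16% had their summit in a promoter, against a mean of 2.16% and at most 2.43% over 100 circular shifts (permutation p = 0.0099). In the replicated list, 15.8% of summits lay in promoters. Shifts can also land in assembly gaps, where no peak can be called, and are not matched on GC content. The excess therefore does not show that these peaks carry the mark. Part of the weaker peaks thus lay at places that the stronger ones favour.

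Chromosome X had 1.12 replicated peaks per Mb against 34.6 on the autosomes together. Sequence composition argues against being the whole cause: the 20 most similar autosomal 1 Mb bins in GC content, gene number and repeats predicted 1534 peaks on chromosome X where 182 summits were counted in the bins used, a ratio of 0.119, while each autosome predicted from the others had a ratio between 0.860 and 1.16. A lower copy number in pools of both sexes stays open, although the factor of 0.75 or more set beforehand for it was not met. A lower factor was set to leave it open, so too large a deficit could not count against it. Scaling all autosomal signal values by 0.504 would leave the observed X share above the 5th percentile of signal (0.586 for the composition-matched share), but a factor of 0.75, that of an equal mix of sexes, would leave 50.8%; that model is an assumption, and the sex ratio and the peak caller's background are not known. A single active X per cell may add to it, as a hypothesis without a test here, and no biological explanation was tested because the pools are not split by sex.

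Genes of the Notch, retinoic acid, BMP and Wnt lists lay in more H3K4me1 than density-matched genes. With matching on bins of GC content, 4 of 4 lists kept an adjusted permutation p below 0.05, at smaller ratios for each. Regional GC content at the resolution of these bins is thus not the whole of it. Covered kb followed GC content within each density bin too (Spearman rho 0.706 to 0.839). GC differences left inside a bin may therefore still contribute. Against density-matched genes, a couple of long loci alone are not the whole of it either. Without their 2 largest loci, 4 of 4 lists had a permutation p below 0.05, adjusted over these 4 lists only. The ratios were 2.27 for Notch, 1.74 for retinoic acid (adjusted permutation p = 0.0265), 2.03 for BMP and 2.07 for Wnt. This removal was not combined with matching on GC content, so both explanations acting together stay open. For retinoic acid, the remaining mean of 6.57 kb lay inside the GC-matched draws for its full list (95% of draws 3.70 to 8.47 kb). For smooth muscle, matching on GC content took the ratio from 2.02 to 1.40 and ended the call, because matched genes then had a mean of 5.46 kb (95% of draws 3.65 to 7.71 kb) in place of 3.78 kb (1.92 to 6.19 kb); what remains (permutation p = 0.0368 before adjustment) stays open. No biological explanation was tested, since the series has 1 tissue and stage.

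More TSSs were covered in replicate 2 than in replicate 1, 8.40% against 6.25%. A different extent of the lists is argued against, as replicate 2 covered only 1.01 times the sequence of replicate 1 at equal length, while the share of TSSs differed 1.34 times. GC content of the loci stays open. Across genes, the difference in covered kb between replicate 2 and replicate 1 went with GC content in every density bin (Spearman rho 0.133 to 0.379). Each rho was above the level set beforehand for this explanation, so that prediction was met. Covered kb itself followed GC content in each density bin (Spearman rho 0.706 to 0.839), and the test used a difference in kb. A slightly larger coverage in replicate 2 could thus raise rho without any bias by GC content. The test also covered whole windows and not the TSS itself. At equal list length, promoters held 14.8% of summits in both replicates. The ratio of covered TSSs was 1.16, 1.47 and 1.32 over 3 equal bins from low to high GC content, which is not a steady trend. That comparison over 3 bins, chosen after results were seen, and the limits of the first test are why the question stays open. The pools also differ in embryos and technical replicates, and no biological explanation was tested.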

How the results depend on the processing

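The run on autosomes only was chosen after the data were seen. The overlap of the replicates and the location of summits kept their direction and their side of the threshold in all 40 alternative values. Of 330 alternative values for the gene lists, 281 kept both, 15 lost a call, 9 gained one and 25 turned direction, in lists that had not passed. The Notch, retinoic acid, BMP, olfactory and vomeronasal lists passed under every alternative run. The stomach lists were not distinguishable from those of other organs in any alternative of that comparison, none of which matched on gene density. With GC matching, ratios were 1.60 for gastric mesenchyme, 1.40 for smooth muscle and 1.37 for forebrain neurons (calls lost), and 0.824 for gastric epithelium, 0.844 for squamous forestomach, 0.933 for mesothelium, 0.983 for pancreas, 0.687 for cardiac muscle and 0.963 for skeletal muscle (turned below 1). For gastric mesenchyme the unadjusted permutation p barely moved (0.0127 before and 0.0141 with GC matching). The cause of these and the following changes was not tested. Without matching, calls were lost for gastric mesenchyme (1.15), Wnt (1.57) and forebrain neurons (1.24) and gained for Hox groups 1 to 8 (3.33) and housekeeping genes (1.65). Windows of 20 kb gave Hedgehog 1.91 (gained), enteric nervous system 1.29, mesothelium 0.777, intestine 1.11 and kidney 1.09 (turned). Forebrain neurons (2.18), gastric mesenchyme (2.10) and smooth muscle (1.85) kept their calls at 20 kb. Liver was then at 0.283 and still did not pass (adjusted permutation p = 0.0608). Windows of 100 kb gave gastric mesenchyme 1.67 and forebrain neurons 1.29 (lost), Hedgehog 1.96 (gained), and differentiated gastric products 1.25, enteric nervous system 1.08, intestine 1.17 and kidney 1.03 (turned). Counts of peaks gave gastric epithelium 1.61, Hedgehog 1.75 and Hox groups 1 to 8 1.90 (gained), forebrain neurons 1.53 (lost), and enteric nervous system 1.04 and intestine 1.02 (turned). Without promoters, gastric mesenchyme (1.83) and forebrain neurons (1.57) lost their calls and mesothelium (0.943) and Hox groups 9 to 13 (0.963) turned. With each member as its own locus, Hox groups 1 to 8 (2.05) and Zfp-named genes (0.699) gained a call. Neighbouring members that share a window then count as independent. On autosomes only, gastric mesenchyme (1.67) and forebrain neurons (1.65) lost theirs. At a −log10 q of at least 2, intestine was at 1.00, and the replicates kept 75318 and 74720 peaks. The rank correlation of signal was then 0.348, and 0.383 for −log10 p in place of signal. Of the 20 longest domains, 10 were shared with joining within 1 kb and 10 with the longer joining distance. In the lists of single replicates, ratios ran from 1.80 to 1.88 for gastric mesenchyme, 1.62 to 1.86 for forebrain neurons (lost in replicate 1), 0.949 to 1.06 for differentiated gastric products, 0.978 to 1.13 for enteric nervous system, 0.892 to 1.02 for intestine, 0.837 to 1.09 for kidney, 0.931 to 1.05 for squamous forestomach and 0.997 to 1.18 for Hox groups 9 to 13. Over the same lists, 6.25% to 8.40% of TSSs were covered, 0.373 to 0.519 of the highest share, and 12 to 13 of the longest domains were shared. No paired analysis was possible because the series has 1 group. Depth is unknown, so a gene without a peak is one at which none was called, not one shown to lack the mark.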

Other observations

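The highest-ranked skeletal muscle genes lay in a region of chromosome 7 with many peaks. Tnni2 and Tnnt3, which encode fast skeletal muscle troponins, neighbour Lsp1 and Mrpl23, and the imprinted genes H19 (142575529 to 142578143) and Igf2 (142650766 to 142666816) follow at higher coordinates. Peaks covered 13.4 of the 34.1 kb of Lsp1, 5.05 of the 8.06 kb of Mrpl23, 3.71 of the 17.2 kb of Tnnt3 and 0.723 of the 2.60 kb of Tnni2. In H19, 1.00 of 2.62 kb was covered, and in Igf2 3.83 of 16.1 kb. Most of the 36.9 kb in the window of Tnnt3 was thus outside its own body. H19, Igf2 and Lsp1 were named after their values were seen.

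In each of the 4 Hox clusters, genes of paralog groups 1 to 8 had more covered kb than those of groups 9 to 13. The means were 17.4 and 11.8 kb in the Hoxa cluster, 20.4 and 6.32 kb in Hoxb, 9.27 and 6.07 kb in Hoxc, and 10.4 and 9.31 kb in Hoxd. The exact sign-flip test over clusters gives p = 0.125, the smallest that 4 clusters allow, so the difference cannot pass a threshold of 0.05 here. Each pool's own list had the same direction in each cluster. Of the 183 replicated peaks on chromosome X, 35 had Bcor, which encodes a transcriptional corepressor, as the nearest protein-coding gene, 12 Pja1, 11 the histone variant gene H2al1j and 9 Efnb1, which encodes an ephrin ligand. Around Barx1 and Gata4, known regulators of stomach development, 1.87 and 6.22 kb and 2.86 and 6.57 kb were covered in replicates 1 and 2 at equal list length. With 1 value per pool these gaps have no test, and the means of whole lists were close, at 3.59 and 3.91 kb for gastric epithelium and 3.47 and 3.70 kb for gastric mesenchyme. Bcor, Pja1, H2al1j, Efnb1, Barx1 and Gata4 were singled out after their values were seen.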
